A study of Mus musculus with 6 samples.

How the data were processed

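The series holds 6 RNA-seq libraries from mouse cerebral cortex. Per the labels, the libraries fall into 3 cell types (excitatory neurons, inhibitory neurons, astrocytes), each with 1 library from each of 2 reciprocal F1 crosses called F1i and F1r. In a reciprocal cross the strains of mother and father are exchanged, so that an allele's parent of origin can be told from its strain. The labels do not name the strains, and the alleles are called here the allele inherited from the father in F1i and the other allele. Per the labels' protocols, RNA was extracted with the miRNeasy Micro kit from cells described as single cells, and libraries were made with the SureSelect strand-specific kit. How cells of each type were collected is not given in the sources used here. The labels also give a tracking number. The excitatory F1i library and the inhibitory F1i library each have a number of their own, and the other 4 libraries share the remaining one.

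The gene tables hold FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) that the authors deposited for each library, with a status flag. TopHat, Cufflinks and the mouse genome build GRCm38 are named in the submitters' processing notes; their versions, settings and order are not given in the sources used here. Of 43437 gene identifiers, 59 stood at 2 loci and their values were added, and 6 were left out because a library flagged them as failed. The remaining 43431 were used. The FPKM sum per library ran from 8515710 to 12924800, and the mitochondrial transfer RNA mt-Tg alone took 38.3% to 67.5% of it. The number of genes at an FPKM of at least 1 was 14039 and 13566 in the excitatory pair, 14616 and 14354 in the inhibitory pair, and 14020 and 13852 in the astrocyte pair (F1i first in each pair). FPKM has no read counts behind it in these tables, so no counting error is given for it. An FPKM of exactly 0 can be a failed estimate: mt-Rnr1 was listed at 0 in the excitatory F1i library and at 119720 in the excitatory F1r library. Such genes are called listed at 0 and get no fold change.

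The allele tables hold 1 entry per transcript and parental allele, with the column names that mmseq writes, per the file headers. The abundance estimate of each allele is on a natural log scale, per the file headers, and was deposited with a count of unique hits, which are whole-number read counts that the authors obtained for that transcript and allele alone. The authors also deposited a natural log ratio of the 2 parental alleles for each transcript and their own list of transcripts past 2 SD. The strain sequences and mmseq settings are not given in the sources used here. A further deposited expression column was not used, because it raises 10 (110 in the astrocyte F1i library) to the power of the natural log estimate. Unique hits summed to 4732388, 2617208, 3149416, 3541702, 2726292 and 2648464 over all transcripts (excitatory F1i and F1r, inhibitory F1i and F1r, astrocyte F1i and F1r). Hits on the 74946 autosomal transcripts with separate alleles were 946197, 465388, 934396, 1034163, 797366 and 589253 in the same order. Intervals on shares of hits are 95% exact (Clopper-Pearson) binomial intervals, and the upper limit given for 0 hits is 3 counts of the total. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Isoform tables and the authors' enrichment tables were not used here.

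Expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), after keeping the 16000 genes with an FPKM of at least 1 in at least 2 libraries. All 6 libraries entered 1 fit with a mean per cell type, empirical Bayes moderation with a trend, and no block. The contrast of the crosses added the cross to that fit. Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Each cell type has 2 libraries, 1 from each cross, so the spread between them includes the cross. Nothing says whether the libraries of the 3 cell types in a cross came from separate animals, so the p-values measure only the spread between these samples. The 21 gene lists were tested with limma's camera (preset correlation 0.01, with an estimated correlation as an alternative) and fry, adjusted over the lists of a contrast. Lists with fewer than 5 tested genes were left out of that test. Of 386 list genes, 377 were found by symbol.

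For the allele tests each gene was represented by its transcript with the most unique hits. The response was log2(paternal/maternal), converted from the natural log estimates, for the 3597 autosomal genes with at least 10 unique hits in each of the 6 libraries. A limma fit with the strain coded by cross gave a parental effect and a strain effect, with the mean hits as the trend covariate, and a moderated F-test asked whether the parental effect differed between the 3 cell types. Positive strain effects mean more of the allele inherited from the father in F1i. Where an allele has 0 hits, its deposited estimate is set by the authors' model and not by reads, and log2 ratios near 20 measure no fold. Imprinted genes with at least 10 hits in total were tested by an exact sign-flip permutation test over the 6 libraries (64 flips, two-sided, smallest possible p 0.03125). Genes past 2 SD in both crosses, with the SD taken over all transcripts of a library, and the share of X-linked hits are descriptions without a replicate test.

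Mitochondrial copies in the nuclear genome were found by comparing 16-mers of GENCODE M21 transcripts (GRCm38) with the mitochondrial transcripts. Genes sharing at least 10% of their 16-mers were called copies. This and the position of 35 Mb used on chromosome 19 were chosen after the data were seen. Tables were handled in Python 3.11.15 with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

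The groups, tests, gene lists and the rule for named genes were chosen before the data were examined. The rule takes, for each cell type contrast, up to 4 members of each list with the largest change among those passing, and the 10 largest changes in each direction among called genes whose 2 libraries of the higher group had an FPKM of at least 5 and lay above both libraries of the lower group. Symbols made of Gm and a number, symbols ending in Rik, and mitochondrial genes were left out. For the crosses it takes 5 genes per direction in the same way, and for alleles the imprinted lists, the 10 largest parental effects with the same sign in all 6 libraries, the 5 largest strain effects in each direction, the genes Grb10, Ube3a and Gnas, and the 10 smallest p-values of the F-test. Genes named outside the rule are said to be so. Some genes that the rule takes are not reported here.

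Each fit was tested on simulated data with 200 changed genes. For astrocytes against excitatory neurons, over 16000 genes, 0%, 0% and 91.0% of the changed genes were recovered at log2 changes of 1, 2 and 4, with 3.70% false calls at 4. For the crosses the recovered shares were 0%, 30.5% and 92.5%, with 12.9% false calls at 2 and 10.6% at 4, above the adjusted threshold of 0.05. For the parental effect, over 3597 genes, they were 32.0%, 83.5% and 95.5%, with at most 4.50% false calls. For the strain effect they were 29.5%, 81.5% and 95.0%, with at most 5.23% false calls. A parental effect in astrocytes alone was recovered in 0%, 0% and 24.0% of genes, with 12.7% false calls at 4. Alternatives tried were another pseudocount, no filter on low values, median rescaling, quantile normalization, no trend, the cross as a block, the 4 libraries of 1 tracking number, other minima of hits, ratios of hits in place of the estimates, sums over transcripts, centring, and leaving out each library in turn. Later additions were protein-coding genes alone, the fit without both libraries labelled inhibitory neurons, and the fit without chromosome 19.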

Results

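RNA from mouse cerebral cortex was profiled in 6 libraries, 2 for each of 3 labelled cell types, with 1 library of each pair from the F1i cross and 1 from the reciprocal F1r cross. The labels imply 3 comparisons between cell types, 1 between the crosses, and a comparison of the paternal with the maternal allele in every library. Allele-resolved unique hits on autosomes ranged from 465388 in the excitatory F1r library to 1034163 in the inhibitory F1r library. Across protein-coding genes, which are not independent replicates, the Pearson correlation of log2(FPKM + 1) within a pair was 0.924 for excitatory neurons, 0.936 for inhibitory neurons and 0.958 for astrocytes. Between cell types it ran as high as 0.928, for the excitatory F1r with the astrocyte F1i library, and as low as 0.521, for the inhibitory F1i with the astrocyte F1r library.

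Marker genes did not follow the labels in a simple way. Microglial genes were the most abundant of the marker lists in both libraries labelled inhibitory neurons, where the list of 12 genes had a median FPKM of 856 (F1i) and 460 (F1r). The same list stood at 67.9 and 6.87 in the excitatory pair and at 1.64 and 0.551 in the astrocyte pair. The libraries labelled inhibitory neurons are therefore named by their label throughout, and directions drawn from them are directions for the libraries so labelled. Excitatory neurons and astrocytes are names by label as well, since markers of other cell types were high in those libraries too.

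The list of inhibitory neuron markers had medians of 6.27 and 5.78 in the excitatory pair and of 7.48 and 8.55 in the astrocyte pair. As a list, though not for every member, these markers were lowest in the pair labelled inhibitory neurons, at 0.944 and 2.63. Gad1, which makes the transmitter GABA, had an FPKM of 2.50 (F1i) and 6.76 (F1r) there, 13.5 and 21.2 in the excitatory pair, and 31.8 and 48.6 in the astrocyte pair. Dlx1, a transcription factor of the interneuron lineage, had 6.47 and 17.3, 91.7 and 88.7, and 181 and 184 in the same order. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, was low in all 6 libraries, at 4.34 and 9.39 in the excitatory pair, 3.21 and 1.40 in the inhibitory-labelled pair and 1.52 in each astrocyte library. Camk2a, a kinase of excitatory neurons, had an FPKM of 19.6 and 27.5 in the excitatory pair against 8.44 and 10.2 in the astrocyte pair. The astrocyte list of 24 genes had medians of 76.6 and 82.3 in the astrocyte pair, 77.1 and 38.9 in the excitatory pair, and 3.46 and 10.5 in the inhibitory-labelled pair. Slc1a3, an astrocytic glutamate transporter, stood at 409 and 220 in the excitatory pair and at 440 and 458 in the astrocyte pair.

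Myelin genes were prominent in the excitatory pair. The oligodendrocyte lineage list had medians of 165 and 185 there, 34.7 and 70.9 in the inhibitory-labelled pair, and 75.2 and 23.2 in the astrocyte pair. Endothelial and mural genes stayed at medians between 0.217 and 0.867, and the blood list at medians between 1.63 and 9.09. Immediate early and heat shock genes, which respond to activity and to tissue handling, had medians of 93.8 and 94.3 in the inhibitory-labelled pair, 7.20 and 6.77 in the excitatory pair, and 14.1 and 12.1 in the astrocyte pair. Fos, a member of that list, reached 1410 and 1086 in the inhibitory-labelled pair against 54.3 and 48.8 in the excitatory pair.

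**Figure D1:**
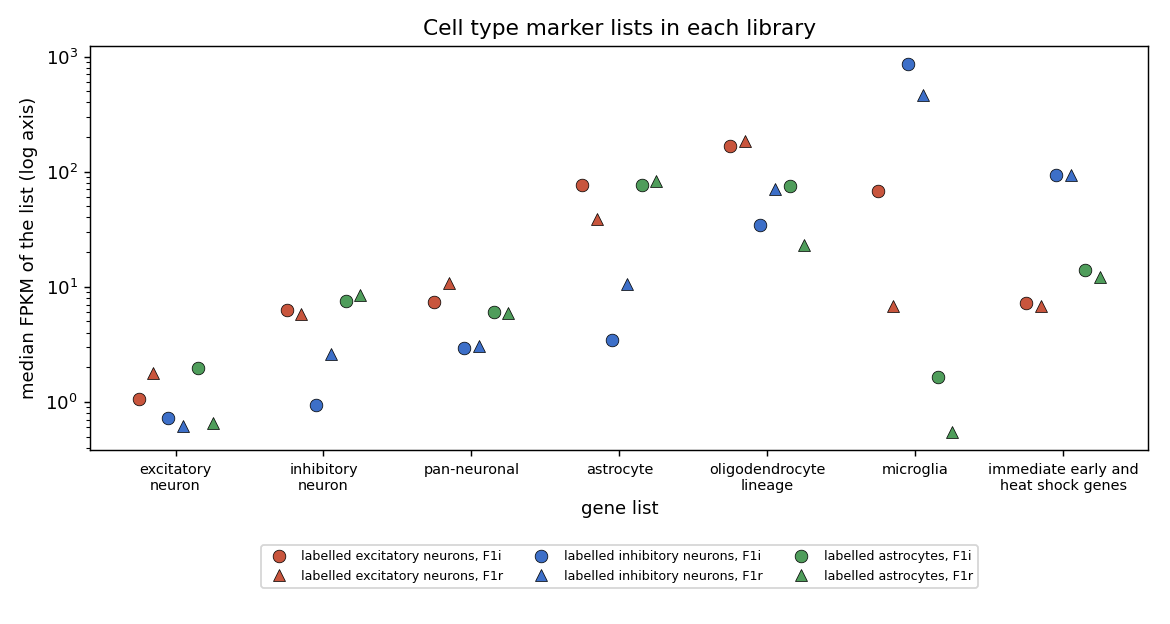
Median FPKM (log axis) of 7 gene lists in each of the 6 libraries; circles are F1i, triangles F1r, and colours give the labelled cell type. The microglia list lies at 856 and 460 in the pair labelled inhibitory neurons and at 1.64 and 0.551 in the astrocyte pair.

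Astrocytes were compared with the libraries labelled inhibitory neurons. Microglial genes were lower in astrocytes and astrocyte, interneuron and receptor genes higher. Cx3cr1, the fractalkine receptor of microglia (chromosome 9, 119901616 to 120068283, GRCm38 here and throughout), fell by 8.69 ± 0.92 (SE) on the log2 scale, from an FPKM of 973 and 753 to 1.64 and 0.626 (limma, adjusted p = 0.0061). Csf1r, the receptor for the growth factor that microglia need, changed by -8.65 ± 0.90, the protease gene Ctss by -8.53 ± 0.94 and P2ry12, a purinergic receptor of resting microglia, by -8.49 ± 0.79. The other genes among the 10 largest decreases were C1qc (-8.43), Selplg (-8.04), C1qa (-8.03), Fcrls (-7.96), Tmem119 (-7.89) and C1qb (-7.80), with limma adjusted p-values up to 0.00748. All 12 microglial genes were lower (12 also when adjusted over the list alone; camera adjusted p = 4.6e-08; adjusted p = 0.380 with an estimated correlation).

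In the opposite direction, Slc6a11, a GABA transporter of astrocytes (chromosome 6, 114131241 to 114249886), was higher by 5.47 ± 0.63 on the log2 scale, at an FPKM of 213 and 228 in astrocytes against 2.23 and 6.71 (adjusted p = 0.0062). Fabp7, a fatty acid binding protein of radial glia and astrocytes, was higher by 5.34 ± 0.64, Gja1, the gap junction protein connexin 43, by 4.50 ± 0.89, and Nrxn3, a presynaptic adhesion protein, by 4.46 ± 0.31. Frzb, a secreted Wnt antagonist, had an FPKM of 30.0 and 17.2 against 0.308 in the inhibitory F1r library and was listed at 0 in the inhibitory F1i library (adjusted p = 0.0060). The microRNA genes Mir1905 (314 and 201 against 8.95 and listed at 0, adjusted p = 0.0135) and Mir1192 (20.3 and 44.3 against 0.668 and listed at 0, adjusted p = 0.0133) were higher too. Mir204 had an FPKM of 106 and 102 in astrocytes and was listed at 0 in both inhibitory-labelled libraries (adjusted p = 0.0457), and Mir344 had 26.5 and 17.9 and was listed at 0 in both. MicroRNA genes are shorter than a library fragment, and their FPKM is uncertain. Of 24 astrocyte markers, 21 were higher and 0 lower (22 higher adjusted over the list alone), with Slc4a4 at 4.12 ± 0.59, Ntsr2 at 4.06 and Aqp4, the water channel of astrocyte endfeet, at 3.99 ± 0.65 (camera adjusted p = 3.3e-10; adjusted p = 0.380 with an estimated correlation).

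Interneuron markers were also higher in the astrocyte libraries, for 14 of 19 genes (15 adjusted over the list alone). Npy, a neuropeptide of interneurons (chromosome 6, 49822710 to 49829507), was higher by 5.14 ± 0.56, at an FPKM of 109 and 50.5 against 2.33 and 0.380 (adjusted p = 0.0061), followed by Dlx1 (3.97 ± 0.46), Dlx5 (3.69) and Dlx2 (3.68). Camera gave this list an adjusted p of 4.6e-08 (adjusted p = 0.273 with an estimated correlation). Of 15 pan-neuronal markers 8 were higher (9 adjusted over the list alone), led by the microtubule protein gene Map2 (3.46 ± 0.46), Stmn2 (3.17), Uchl1 (2.43) and Celf4 (2.40), with a camera adjusted p of 1.3e-04 (adjusted p = 0.273 with an estimated correlation). Among 13 excitatory markers, Rorb, a transcription factor of layer 4 neurons, was higher by 2.54 ± 0.36, Fezf2 stood at 2.42 and 2.36 against listed at 0 and 0.374, and 11 did not pass (2 adjusted over the list alone; camera adjusted p = 0.121). No oligodendrocyte gene of 16 passed (0 by limma over all genes and over the list alone). That list's median log2 change was -0.19, its mean 0.03 and its camera direction upward (adjusted p = 0.744). Of 7 endothelial and mural genes 3 were higher (Vtn, 3.58 ± 0.30; Cldn5, 2.35; Pdgfrb, 1.55) and the adhesion protein gene Pecam1 was lower by -5.47 ± 0.72 (4 adjusted over the list alone; camera adjusted p = 0.0540). The 4 blood genes did not pass and were too few for camera.

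Receptor, channel and release genes moved in the same direction as the interneuron list. Ionotropic glutamate receptor genes were higher for 8 of 12 (9 adjusted over the list alone), with Gria2 at 3.52 ± 0.43, Grin2c at 3.18, Grik3 at 3.02 and Grik5 at 2.39 (camera adjusted p = 1.2e-05; adjusted p = 0.273 with an estimated correlation). GABA-A receptor genes were higher for 7 of 9 (7 adjusted over the list alone), among them Gabrb1 (3.16 ± 0.41), Gabrg1 (2.32) and Gabra4 (1.40), with a camera adjusted p of 8.9e-04 (adjusted p = 0.273 with an estimated correlation). Synaptic vesicle genes were higher for 7 of 19 (8 adjusted over the list alone), among them Syn1 (1.68), Unc13a (1.64) and Pclo (1.54; camera adjusted p = 0.00136; adjusted p = 0.384 with an estimated correlation). Voltage-gated channels had 9 higher and 1 lower of 18 (10 and 1 adjusted over the list alone): the potassium channel gene Kcnd3 at 2.84, Cacna1c at 2.46 and Kcnc1 at 2.43 were among the higher ones (camera adjusted p = 2.6e-04; adjusted p = 0.273 with an estimated correlation). Notch and BMP genes were higher for 9 of 17 (10 higher and 1 lower adjusted over the list alone), with Id4 at 3.29, Hey2 at 3.07 and Id3 at 2.65 (camera adjusted p = 6.6e-05; adjusted p = 0.281 with an estimated correlation). In the same contrast the microglial list went the opposite way, with a median change of -7.96. Directional fry gave an adjusted p of 0.0173 for the microglial list, 0.0162 for the inhibitory markers and 0.143 for the excitatory markers.

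Immediate early and heat shock genes were lower in astrocytes for 19 of 24 members (20 adjusted over the list alone). Zfp36, which destabilizes inflammatory mRNAs, changed by -5.49 ± 0.71, the stress transcription factor gene Atf3 by -5.40 ± 0.56, Btg2 by -4.14 and Jun by -3.69 ± 0.50 (camera adjusted p = 8.3e-10; adjusted p = 0.273 with an estimated correlation). Glycolysis genes went both ways: the hexokinase gene Hk2 changed by -4.19 ± 0.37, while Aldoc, the brain aldolase, was higher by 3.15, Pfkp by 2.30 and Pfkm by 2.20, so that 3 were higher and 4 lower of 18 (the same numbers adjusted over the list alone; median 0.00, mean -0.12, camera adjusted p = 0.744). Cholesterol synthesis genes were higher for 3 of 18, among them Sqle by 1.87 and Hsd17b7 by 1.68 (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.7e-04; adjusted p = 0.398 with an estimated correlation). Of 14 fatty acid oxidation genes 1 was lower, Acads at -1.74 (0 adjusted over the list alone; camera adjusted p = 0.723), and of 20 nuclear genes of oxidative phosphorylation 0 passed either way (camera adjusted p = 0.118). Paternally expressed imprinted genes were higher for 4 and lower for 1 of 24 (the same adjusted over the list alone), among them Nnat (3.53 ± 0.31), Mest (3.00), Peg3 (2.18) and Ndn (1.89; camera adjusted p = 0.0112; adjusted p = 0.273 with an estimated correlation). Of 20 maternally expressed genes 3 were lower, Pon3 (-4.16 ± 0.35), Gatm (-2.16) and Pon2 (-1.31; 3 adjusted over the list alone; camera adjusted p = 0.173), and of 6 isoform-dependent imprinted genes Adam23 was higher by 2.19 (1 adjusted over the list alone; camera adjusted p = 0.0440; adjusted p = 0.385 with an estimated correlation).

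In all, limma called 4011 of 16000 genes between astrocytes and the libraries labelled inhibitory neurons, 1843 higher and 2168 lower, against a median log2 change of all genes of -0.11. After rescaling each library to a common median 2242 were higher and 2174 lower, and after quantile normalization 2320 and 2147, so that the larger of the 2 numbers changed sides. Without the astrocyte F1i or the astrocyte F1r library 0 genes were called, and without the inhibitory F1i library 1448. Among the 4 libraries of 1 tracking number 946 genes were called, with a single inhibitory-labelled library that is assumed to vary like the astrocyte pair.

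Excitatory neurons were compared with the libraries labelled inhibitory neurons in the same way. Klf2, a transcription factor of endothelium and leukocytes (chromosome 8, 72319033 to 72321656), changed by -5.54 ± 0.66, from an FPKM of 194 and 212 in the inhibitory-labelled pair to 7.07 and 1.37 (limma adjusted p = 0.0150). Zfp36 changed by -5.31 ± 0.71, Rgs1 by -5.22 ± 0.95, Tmem119 by -5.22 ± 0.99 and the myeloid transcription factor gene Cebpa by -5.16 ± 0.50. P2ry12 changed by -5.12 ± 0.79 and Selplg by -5.10 ± 0.92. The microRNA genes Mir27a (29.3 and 80.4 against 0.246 and listed at 0) and Mir24-2 (16.1 and 129 against 0.650 and listed at 0) are also among the 10 largest decreases. They lie within the same stretch of chromosome 8 (84208672 to 84208758 and 84208815 to 84208921), where fragments can cover both. All 12 microglial genes were lower (12 adjusted over the list alone), Csf1r by -5.01 and Cx3cr1 by -4.93, with a camera adjusted p of 7.8e-06 (adjusted p = 0.349 with an estimated correlation). Of 24 immediate early and heat shock genes 21 were lower, Atf3 by -4.87, Btg2 by -4.85 and Junb by -4.74 (23 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.2e-12; adjusted p = 0.234 with an estimated correlation).

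Hist1h2af, a replication-dependent histone gene (chromosome 13, 23533906 to 23534304), was higher in excitatory neurons than in the inhibitory-labelled pair by 4.40 ± 0.46, at an FPKM of 446 and 346 against 11.5 and 27.0 (adjusted p = 0.0150), and the histone genes Hist1h1b and Hist1h3b by 3.74 ± 0.43 and 3.50 ± 0.30. Histone genes have close copies that can share reads. Ccnd2, a cyclin of the G1 phase, was higher by 3.52 ± 0.52, and the adhesion protein gene Lsamp by 3.48 ± 0.63. Gja1 (3.80 ± 0.89), Slc1a2 (3.76 ± 0.85), Slc6a11 (3.62 ± 0.63), Fabp7 (3.55 ± 0.64) and Ntsr2 (3.54 ± 0.76) completed the 10 largest increases. Of 24 astrocyte markers 21 were higher, including Atp1b2 at 3.40 (23 adjusted over the list alone; camera adjusted p = 1.5e-11; adjusted p = 0.317 with an estimated correlation). The 16 oligodendrocyte genes had a median change of 1.79 and 0 passed limma over all genes or over the list alone (camera adjusted p = 5.1e-05; adjusted p = 0.401 with an estimated correlation).

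Only 2 of 13 excitatory markers were higher in the excitatory pair than in the inhibitory-labelled pair by limma, Rorb by 2.09 ± 0.36 and Camk2a by 1.59 ± 0.32 (2 adjusted over the list alone; camera adjusted p = 0.00222; adjusted p = 0.300 with an estimated correlation). Inhibitory markers were higher there for 9 of 19, among them Dlx1 by 2.96 ± 0.46 and Dlx2 by 2.83 (14 adjusted over the list alone; camera adjusted p = 3.5e-08; adjusted p = 0.277 with an estimated correlation). Pan-neuronal markers were higher for 9 of 15, Map2 by 2.62, Uchl1 by 2.36, Stmn2 by 1.95 and Snap25 by 1.90 (12 adjusted over the list alone; camera adjusted p = 5.6e-07; adjusted p = 0.234 with an estimated correlation). Glutamate receptor genes were higher for 7 of 12, among them Grin2c (2.68), Gria2 (2.49), Grik5 (2.20) and Grik2 (2.02; 8 adjusted over the list alone; camera adjusted p = 6.3e-06; adjusted p = 0.277 with an estimated correlation). GABA-A receptor genes were higher for 3 of 9, among them Gabrb1 (2.68) and Gabra4 (1.01; 6 adjusted over the list alone; camera adjusted p = 6.7e-04; adjusted p = 0.234 with an estimated correlation). For synaptic vesicle genes the number was 7 of 19, including Syn2 (1.76), Syn1 (1.49) and Rab3a (1.48; 10 adjusted over the list alone; camera adjusted p = 7.6e-06; adjusted p = 0.286 with an estimated correlation). Voltage-gated channels had 2 higher, Kcna2 (1.91) and Kcnc1 (1.48), and 1 lower of 18 genes (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.1e-04; adjusted p = 0.277 with an estimated correlation). The microglial list went the opposite way to these groups, by a median of -4.74. Directional fry gave an adjusted p of 0.0539 for the microglial list, 0.0383 for the inhibitory markers and 0.0611 for the excitatory markers.

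Of 18 cholesterol synthesis genes 5 were higher in the excitatory pair, Msmo1 by 2.29, Sqle by 1.84, Cyp51 by 1.77 and Fdps by 1.75 (14 adjusted over the list alone; camera adjusted p = 4.1e-07; adjusted p = 0.300 with an estimated correlation). The oligodendrocyte list had a median of 1.79 and the microglia list of -4.74 in the same contrast. Notch and BMP genes had 6 higher and 1 lower of 17, with Id4 (2.72), Bmpr1b (2.00), Hey1 (1.91) and Id1 (4.56 and 1.91 against listed at 0 and 0.226; 7 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00370; adjusted p = 0.329 with an estimated correlation). Paternally expressed imprinted genes had 5 higher and 1 lower of 24, with Nnat (2.78), Ndn (2.21), Peg3 (1.85) and Snrpn (1.74; the same numbers adjusted over the list alone; camera adjusted p = 0.0110; adjusted p = 0.286 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.39 and 0 of 20 passed limma over all genes or over the list alone (camera adjusted p = 0.00352; adjusted p = 0.329 with an estimated correlation). Glycolysis genes again went both ways, with 3 higher and 4 lower of 18, Hk2 at -3.63, Aldoc at 2.82, Pfkfb3 at -2.11 and Pfkm at 1.81 (4 and 4 adjusted over the list alone; median 0.08, mean -0.06, camera adjusted p = 0.716). Single genes passed in 4 more lists whose camera test did not pass, Acads (-1.62; camera adjusted p = 0.973; 0 adjusted over the list alone), Pecam1 (-3.71; 0.198; 1 adjusted over the list alone), Pon3 (-3.18; 0.660; 1 adjusted over the list alone) and Adam23 (1.64; 0.0702; 1 adjusted over the list alone), and 0 of 4 blood genes did.

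Between excitatory neurons and the libraries labelled inhibitory neurons limma called 3111 genes, 1140 higher and 1971 lower, with a median log2 change of all genes of -0.17. After rescaling each library to a common median the calls were 1892 higher and 1833 lower, and after quantile normalization 1912 higher and 1813 lower. Leaving out the astrocyte F1i, the astrocyte F1r or the inhibitory F1i library gave 0 calls, leaving out the excitatory F1i library 1269 and the excitatory F1r library 1019. Within the 4 libraries of 1 tracking number 0 genes passed, with 1 library for each of these cell types and the spread taken from the astrocyte pair.

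Few genes were called between astrocytes and excitatory neurons. On simulated data this contrast recovered 0% of changed genes at log2 changes of 1 and 2. The small number of calls therefore does not show that the libraries are alike. Frzb (chromosome 2, 80411970 to 80447625) had an FPKM of 30.0 and 17.2 in astrocytes against 0.213 and 0.351 in excitatory neurons, a log2 change of 4.22 ± 0.34 (limma adjusted p = 0.0393). Mir344 (chromosome 7, 61877770 to 61877864) had 26.5 and 17.9 in astrocytes and was listed at 0 in all 4 neuron-labelled libraries (adjusted p = 0.0274). In all, 15 genes were called, all higher in astrocytes. The other 13 have provisional symbols, such as Gm25772, which is outside the rule and was chosen after its values were seen, at 183 and 107 in astrocytes and listed at 0 in the neuron-labelled libraries. At an unadjusted p under 0.05 there were 1758 genes, and the median change of all genes was 0.07. Among protein-coding genes alone, a fit chosen after the data were seen, 5 genes were higher and 1 lower, and 2 of these were among the 15. The count of 15 fell to 0 with no filter on low values and to 1 with a pseudocount of 0.1. The count was 0 without the astrocyte F1i, the astrocyte F1r or the excitatory F1i library, 57 without the excitatory F1r library, and 39 and 38 without the inhibitory F1i and F1r library. It was 43 without both inhibitory-labelled libraries and 0 within the 4 libraries of 1 tracking number.

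By limma 0 members of the 21 lists passed over all genes in this comparison. Adjusted over the list alone, 11 of 12 microglial genes were lower in astrocytes, with Cx3cr1 at -3.76 (adjusted p = 0.345 over all genes), while the excitatory F1i and F1r libraries themselves differed in Cx3cr1, at an FPKM of 74.4 and 9.51. Likewise 6 of 24 immediate early and heat shock genes passed adjusted over the list alone, with Egr1 at 2.10 and Fos at 1.98 (0.235 and 0.275 over all genes), and 2 of 19 inhibitory markers, with Npy at 3.05 (0.331). A single gene did in the endothelial and mural list (Vtn, 2.92), the voltage-gated channel list (Kcnd3, 1.87) and the paternally expressed list (Mest, 2.22), and 0 genes did in the other 15 lists. Camera passed 6 lists: microglia (median -3.20, adjusted p = 1.5e-10), oligodendrocyte lineage (-2.06, 6.2e-08), cholesterol synthesis (-0.45, 0.00413), inhibitory markers (0.85, 0.00358), immediate early and heat shock genes (0.72, 0.00165) and Notch and BMP genes (0.65, 0.00165). Each had an adjusted p = 0.638 with an estimated correlation. In its directional form fry passed no list (lowest adjusted p = 0.137, for GABA-A receptor genes). The astrocyte list itself had a median of 0.42 (camera adjusted p = 0.142), the excitatory list -0.27 (0.0888) and the pan-neuronal list -0.03 (0.627).

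The genes called between the reciprocal crosses were nuclear copies of mitochondrial genes and small RNAs. By limma 18 genes were called between F1r and F1i with cell type as a covariate, 12 higher and 6 lower in F1r, and 1290 had an unadjusted p under 0.05. The median change of all genes was -0.18. With no filter on low values the calls were 0 higher and 4 lower. All 18 have Gm symbols, so the rule named 0 genes, and those named here were chosen after their values were seen. Gm13340, a pseudogene on chromosome 2 (22588103 to 22589647) with 67.5% of its 16-mers in the mitochondrial transcript mt-Co1, had an FPKM of 1762, 708 and 1065 in the F1i libraries of excitatory, inhibitory-labelled and astrocyte cells and 4.67, 1.97 and 3.64 in F1r. Its log2 change was -8.01 ± 0.21 (adjusted p = 0.0118). Its neighbours Gm13341 and Gm13339 changed by -7.75 and -8.08. Gm4076 on chromosome 13 had 659, 573 and 688 in F1i and, in F1r, was listed at 0, 0.728 and 0.702, and Gm11407 on chromosome 4 had 133, 77.6 and 119 in F1i and was listed at 0, 0 and 0.586 in F1r. In the opposite direction Gm29216 on chromosome 1 (24615706 to 24616197), with 97.3% of its 16-mers in mt-Co1, was listed at 0.324, 0 and 0.333 in F1i against 35.8, 14.2 and 32.3 in F1r (adjusted p = 0.0333), and Gm28661 at 0.621, 0 and 0.655 against 10.7, 6.05 and 9.99. Reads from these copies and from the mitochondrial genes cannot be told apart with certainty.

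Among the 16 tested nuclear copies, 7 had at least 90% of their 16-mers in mitochondrial transcripts, and all 7 were higher in F1r in every cell type. All 7 lie in a single stretch of chromosome 1 (24611535 to 24616197) and are not independent of each other. Of the 9 more diverged copies, with 23.3% to 67.5% shared, 7 were higher in F1i in every cell type, and Gm11512 and Gm20594 were not. Among these, Gm13339, Gm13340 and Gm13341 are neighbours on chromosome 2, and Gm11407, Gm11408 and Gm11410 on chromosome 4. The copies made up 7 of the 18 calls, 43.8% of the copies against 0.0635% of other genes. The mitochondrial mRNAs themselves had a median log2 change of 1.31, 1.34 in excitatory, 1.36 in inhibitory-labelled and 1.25 in astrocyte libraries; 10 of 13 were higher in F1r in every cell type, and 0 passed limma. Mt-Co1, a subunit of cytochrome c oxidase, had an FPKM of 1321, 505 and 1176 in F1i and 4574, 2705 and 3950 in F1r (1.99 ± 0.38, adjusted p = 0.555), whereas mt-Atp8 changed by -1.82 (adjusted p = 0.555). In the astrocyte pair, the only pair with 1 tracking number, Gm13340 stood at 1065 and 3.64.

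**Figure D2:**
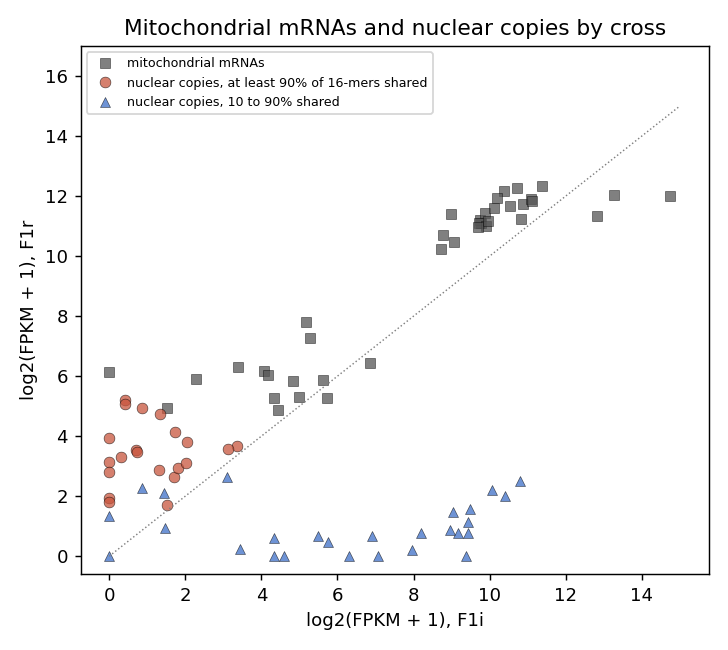
Log2(FPKM + 1) in F1i (x axis) and F1r (y axis) of mitochondrial mRNAs (grey squares) and of nuclear copies sharing at least 90% (red circles) or 10% to 90% (blue triangles) of their 16-mers with mitochondrial transcripts, 1 point per gene and cell type; the dotted line marks equality. All 7 near-identical copies lie above the line in every cell type, and 7 of the 9 diverged copies lie below it.

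Small nucleolar RNA genes of chromosome 7 were also called between the crosses. Gm25156 (59353283 to 59353361) had an FPKM of 2748, 2778 and 758 in F1i and was listed at 0 in all 3 F1r libraries (adjusted p = 0.0240). Its neighbour Gm25648 (59347681 to 59347759) was listed at 0 in F1i and had 31.0, 31.1 and 24.3 in F1r (adjusted p = 0.0161). The remaining 9 called genes are small RNAs that were higher in F1r. Limma passed 0 members of any list in this contrast, over all genes or adjusted over the list alone. Camera passed 8 lists: inhibitory markers (adjusted p = 1.9e-05; adjusted p = 0.543 with an estimated correlation), synaptic vesicle genes (1.8e-04; 0.543), pan-neuronal markers (6.4e-04; 0.543), glutamate receptors (0.00193; 0.543), paternally expressed genes (0.00289; 0.543), voltage-gated channels (0.00329; 0.543) and astrocyte markers (0.0371; 0.948) upward, and microglia (0.00113; 0.827) downward with a median of -1.31. The count of 18 was 0 without any one of the 4 neuron-labelled libraries or without both inhibitory-labelled libraries, 132 without the astrocyte F1i and 136 without the astrocyte F1r library. The excitatory and inhibitory-labelled pairs differ in tracking number as well as in cross, and 1 pair within a number is too few for a test of the cross alone.

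The reciprocal design asks which genes are expressed from the paternal or the maternal copy. Imprinted genes showed it most clearly. Kcnq1ot1, a paternally expressed long noncoding RNA (chromosome 7, 143212155 to 143296549), had 2955 unique hits with 99.3% on the paternal allele (95% exact interval 98.9% to 99.5%), Peg3, a zinc finger gene, 99.0% of 1257 hits (98.2% to 99.4%), and Ndn 100% of 220, where 0 maternal hits allow a share of up to 1.36%. Impact had 90.3% of 321 (86.6% to 93.3%), at 99.1% in excitatory neurons, 78.1% in the inhibitory-labelled pair and 94.7% in astrocytes, Zrsr1 97.3% of 146 and Rasgrf1 89.2% of 111. Meg3, a maternally expressed noncoding RNA (chromosome 12, 109541001 to 109571726), had 98.1% of 413 hits on the maternal allele (96.2% to 99.2%), and Rian, in the same cluster, 100% of 58, with up to 5.17% paternal allowed. Within the astrocyte pair of 1 tracking number Peg3 had 285 paternal and 0 maternal hits in F1i and 329 and 2 in F1r.

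Of 17 paternally expressed genes with at least 10 hits, 14 leaned paternal on average over the libraries (two-sided exact sign test p = 0.0127). Of 18 maternally expressed genes 14 leaned maternal (exact sign test p = 0.0309). By the mean log2 ratio of hits it was 15 in each list (exact sign test p = 0.00235 and 0.00754). Pon2 is counted there with 43.2% maternal hits of 220, and Tssc4, with 50.8% of 61, is not. Several listed genes lie close together, such as Peg3 and Usp29, and all were measured in the same 6 libraries. They are not independent, so the sign test p-values overstate the evidence. At least 90% of hits fell on the textbook allele for 11 paternally and 3 maternally expressed genes. Genes with a weak bias or none were frequent in the maternal list: Cd81 had 52.7% maternal hits of 2607, Gatm 53.7%, Nap1l4 51.8% and Igf2r 51.0%. Ago2 had 57.9% of 959 (54.7% to 61.0%), at 53.1% in excitatory neurons, 51.3% in the inhibitory-labelled pair and 67.4% in astrocytes, a difference that did not pass limma's F-test (adjusted p = 0.995). Copg2 had 52.8% of 458 and leaned maternal in 6 of 6 libraries by the estimates (exact sign-flip p = 0.03125, the smallest possible; adjusted p = 0.119), but in 5 of 6 by hits (exact p = 0.0625). Against the textbook, Rtl1 had 5.88% paternal hits of 17, and Trappc9 97.5% paternal of 40. Rtl1 has an antisense partner and Trappc9 contains the paternally expressed Peg13, and the sources do not say that hits were assigned by strand. In this exact sign-flip test 7 paternally and 2 maternally expressed genes had p = 0.03125 in the textbook direction by the estimates, and 5 and 0 by hits. By the estimates 0 passed adjustment. Sgce, 1 of the 7, had 0 hits on either allele in 3 libraries, where its sign comes from the estimates alone.

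**Figure D3:**
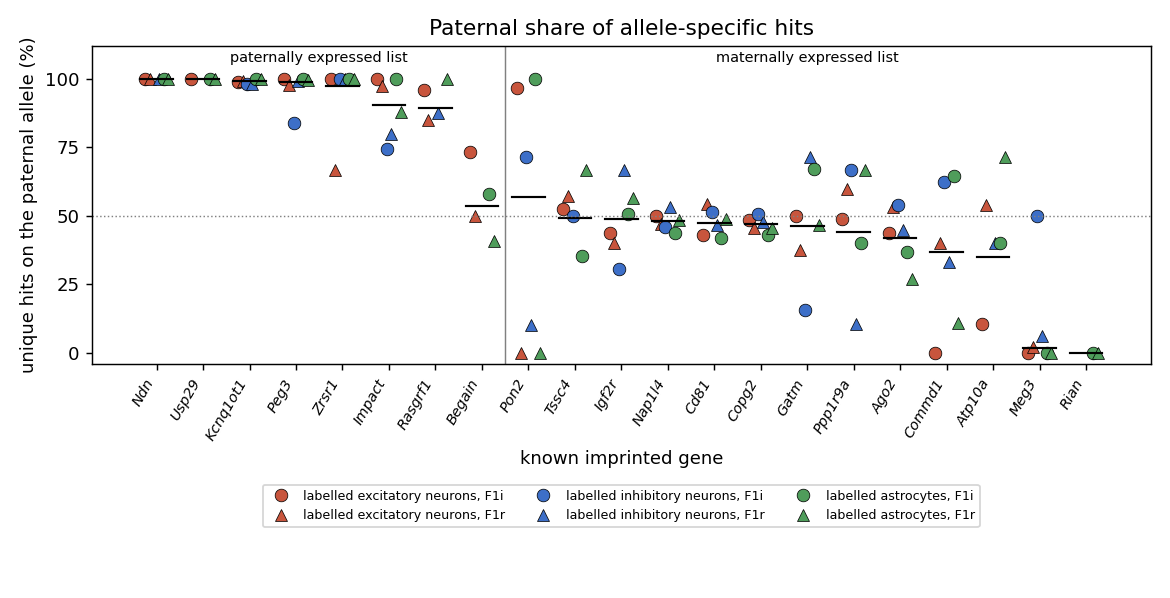
Percent of unique hits on the paternal allele for listed imprinted genes with at least 50 hits; each point is a library with at least 5 hits of the gene, the black bar the share over the 6 libraries, and the dotted line 50%. Kcnq1ot1 (99.3%), Peg3 (99.0%) and Ndn (100%) lie at the paternal end, and Meg3 has 98.1% on the maternal allele.

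Over all 3597 tested genes the parental effect passed limma for 1 gene, Polr2g, and 101 genes had an unadjusted p under 0.05. Polr2g, an RNA polymerase II subunit gene (chromosome 19, 8793129 to 8798557), is outside the rule and was chosen after its values were seen. It had 127, 81 and 111 paternal and 0 maternal hits in F1i and 76, 203 and 77 maternal and 1, 1 and 1 paternal hits in F1r, so its hits followed the strain and 3 of 6 libraries leaned paternal. Its fitted parental effect of 7.48 ± 0.34 (adjusted p = 0.00121) rests on the estimates for 0 against 1 hit. With ratios of hits in place of the estimates, 3 other genes were called and 139 had an unadjusted p under 0.05. These were Kcnq1ot1 at a log2 ratio of 7.31 ± 0.55 (adjusted p = 1.7e-04, paternal in 6 of 6 libraries), Peg3 at 6.54 ± 0.74 (adjusted p = 0.0049, 6 of 6) and H13, a signal peptide peptidase gene, at -2.62 ± 0.36 (adjusted p = 0.0200, maternal in 6 of 6). H13 (chromosome 2, 152669461 to 152708670) is outside the lists and contains the paternally expressed Mcts2. From the estimates, 2 of 12 tested list genes passed adjusted over the list alone, Peg3 and Kcnq1ot1 (0.0394 each; 0.965 over all genes). The number of calls was 3 without the excitatory F1i, 4 without the inhibitory F1i, 3 without the inhibitory F1r, 2 without the astrocyte F1i, 3 without the astrocyte F1r library and 0 without chromosome 19.

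Parental bias was next compared between cell types. Kcnq1ot1 kept the strongest paternal bias in astrocytes, with 1 maternal of 1483 hits (0.0674%), against 0.971% maternal hits in the excitatory and 1.86% in the inhibitory-labelled pair. By ratios of hits this was the 1 gene whose parental effect differed by the moderated F-test of limma (adjusted p = 0.0465; 95 genes at an unadjusted p under 0.05), with log2 ratios of 6.58, 5.63 and 9.72 in excitatory, inhibitory-labelled and astrocyte libraries. The astrocyte value rests on 1 and 0 maternal hits and is set in part by the 0.5 added to each count. Impact was 1 of those 95 genes and did not pass after adjustment (limma adjusted p = 0.998). From the estimates limma's F-test called 0 genes, and 55 had an unadjusted p under 0.05. The 10 smallest p-values belonged to Bard1, Atg2a, BE692007, Cdkn1b, Zfp763, Aldoc, Ppp1r2, Padi2, Topors and Dock5. Bard1, a partner of Brca1 in DNA repair, had 10 and 17 paternal and 0 maternal hits in the inhibitory-labelled pair but both alleles in the other libraries (adjusted p = 0.389), and Atg2a, an autophagy gene, had an adjusted p of 0.724; the other 8 had 0.995. Ube3a, a ubiquitin ligase gene expressed from the maternal allele in neurons, had 50.5% paternal hits of 465 (45.9% to 55.2%; adjusted p = 0.995), at 41.5% in excitatory neurons, 61.7% in the inhibitory-labelled pair and 46.6% in astrocytes, and overlaps an antisense transcript. Gnas had 57.1% paternal hits of 35 (39.4% to 73.7%) and was not tested, and Grb10 had 0 hits. Leaving out the inhibitory F1i or F1r library gave 61 and 37 calls.

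Far more genes were called for strain than for parent of origin. A strain effect in this fit cannot be told apart from reads assigned in error to 1 strain's allele. By limma 297 of 3597 genes had a strain effect, 247 toward the allele inherited from the father in F1i and 50 toward the other, and 290 had the same strain direction in all 6 libraries. Opalin, a myelin membrane gene (chromosome 19, 41062474 to 41077113), had 2239 hits on the allele inherited from the father in F1i and 0 on the other, which allows a share of up to 0.134% (adjusted p = 1.4e-06). Pdcd11 (1808 hits), Sfr1 (1497), Nhlrc2 (1389) and Zfand5 (373), all on chromosome 19, also had 0 hits on the other allele, with upper limits of 0.166%, 0.200%, 0.216% and 0.804%. In the opposite direction were the small RNA genes Rprl3, n-R5-8s1 and Rprl2, with 1 of 2924, 3 of 746 and 1 of 621 hits on the allele inherited from the father in F1i, the cargo receptor gene Tmed2 with 6 of 228, and the ribosomal protein gene Rps12 with 0 of 477. Whether these 5 share hits with related copies elsewhere in the genome was not tested, and their hits are uncertain. Centring each library gave 212 and 85 in place of 247 and 50, and without the astrocyte F1r library 195 genes were called.

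Chromosome 19 held 126 of the 297 calls, all toward the allele inherited from the father in F1i, out of 151 tested genes. That allele took 83.8% of the chromosome's hits (95% exact interval 83.7% to 83.9%), against 49.6% to 53.0% on the 18 other autosomes, where at most 13.9% of tested genes were called. From 35 Mb to the end of the chromosome, the other allele held 0.329% of 93445 hits (0.165% to 0.838% by library), and 59 of 60 tested genes were called. Below 35 Mb it held 21.1% of 304749 hits (16.5% to 23.5% by library), or 11.2% without the abundant noncoding RNA Malat1, and 67 of 91 tested genes were called. Elsewhere in the genome 171 of 3446 genes were called, 121 of them toward the allele inherited from the father in F1i. Correspondingly, the paternal share of all autosomal hits was 54.4%, 53.6% and 54.4% in the F1i libraries of excitatory, inhibitory-labelled and astrocyte cells and 45.3%, 46.0% and 45.5% in F1r. Fitted without chromosome 19, as a choice made after seeing the data, 134 genes had a strain effect by the estimates and 281 by hits.

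**Figure D4:**
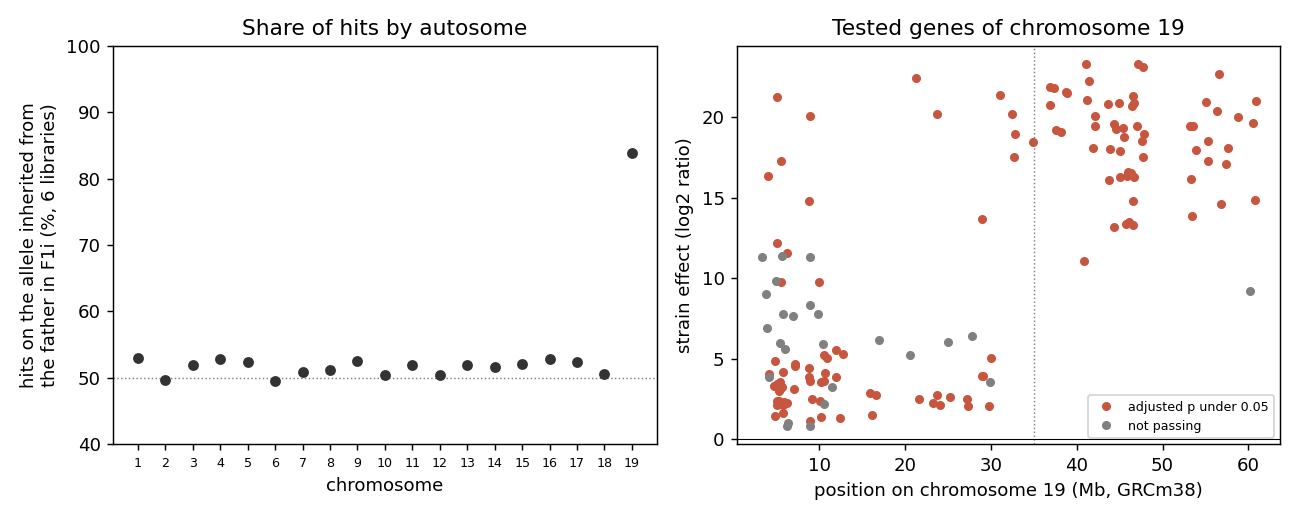
Left: percent of hits on the allele inherited from the father in F1i for each autosome, with 95% exact intervals smaller than the points. Right: strain effect (log2) of the 151 tested genes of chromosome 19 by position in Mb, red where the adjusted p passed; chromosome 19 lies at 83.8% and the other autosomes at 49.6% to 53.0%, and 59 of the 60 genes beyond the dotted line at 35 Mb passed.

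Genes past 2 SD in both crosses of a cell type gave a similar balance. With the same parental allele higher in both crosses there were Ndn in excitatory neurons, Bard1 and Zrsr1 in the inhibitory-labelled pair, and Meg3, Ndn, Rian and Usp29 in astrocytes, out of 4694, 5377 and 5323 genes. With the same strain allele higher there were 102, 106 and 113, of which 78, 63 and 91 lie on chromosome 19. The authors' deposited tables mark transcripts past 2 SD, 6801 and 776 of them in the excitatory F1i and F1r library, 6229 and 1911 in the inhibitory-labelled and 1270 and 751 in the astrocyte pair. All of them have 0 hits on 1 allele, and the median hits of the higher allele are 3 in the excitatory and inhibitory F1i tables and 7 in the other 4. The tables also differ in the fewest hits of the higher allele that the authors accepted. This minimum was 1 in the excitatory and inhibitory F1i tables and 5 in the other 4. The numbers marked, and the overlap of crosses in the neuron-labelled pairs, therefore rest on unlike minima. Of 1334 transcripts marked in both crosses of a cell type in the authors' deposited tables, 1014 (76.0%) follow the strain and 320 the parent, namely 74 of 350 in excitatory neurons, 225 of 744 in the inhibitory-labelled pair and 21 of 240 in astrocytes. The ratio column of the excitatory F1i table is headed as maternal over paternal, but its values have the sign of the paternal minus the maternal estimate and were read so. Read by the header, the 74 and 276 of excitatory neurons would exchange and 812 of 1334 (60.9%) would follow the strain.

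X-linked hits were few. Ddx3y, a Y-linked helicase gene, had an FPKM of 18.0 to 30.9 in the 6 libraries, and Xist, the RNA of the inactive X, at most 0.647. The maternal allele took 100% of 107 hits in the excitatory F1r library (95% exact interval 96.6% to 100%), 99.6% of 530 in the inhibitory F1r library (98.6% to 99.95%) and 92.8% of 138 in the astrocyte F1r library (87.1% to 96.5%). In F1i it took 44.8% of 183 (37.5% to 52.3%), 34.3% of 265 (28.6% to 40.4%) and 31.0% of 113 (22.6% to 40.4%). A male's X comes from the mother. At these Ddx3y and Xist levels the paternal hits in F1i do not show expression from a paternal X. They may be hits assigned to the wrong allele. Paternal hits in F1i came mostly from Dynlt3, a dynein light chain gene, with 46, 86 and 38, and Snx12, a sorting nexin gene, with 22, 65 and 40, and both had 0 paternal hits in F1r. Ndufb11, a gene of respiratory complex I, had maternal hits alone in all 6 libraries. Each library rests on 3 to 5 genes with at least 10 hits. Of the 530 hits in the inhibitory F1r library, 341 are maternal hits of G530011O06Rik, named outside the rule. This gene had 6 maternal hits in the inhibitory F1i library. The share in the inhibitory F1r library and its interval therefore rest mostly on 1 gene.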

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

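The tests of explanations in this part were all chosen after the results were seen. Kcnq1ot1 stands here because its parental bias differed between the cell types in a test of the difference itself: with ratios of unique hits, limma's moderated F-test gave an adjusted p of 0.0465, at 0.0674% maternal hits in astrocytes, 0.971% in excitatory neurons and 1.86% in the libraries labelled inhibitory neurons. From the authors' estimates the same test called 0 genes and 55 had an unadjusted p under 0.05 (61 and 37 calls without the inhibitory F1i and F1r library), and the hits of Kcnq1ot1 on the maternal allele number 22 in all. In astrocytes they are 1 and 0, so that the 0.5 added to each count sets part of the difference.

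Microglial genes were the most abundant markers in the libraries labelled inhibitory neurons. Microglia among the collected cells would bring their other transcripts too, and 19 of 19 tested genes of microglia and myeloid cells outside the list, chosen from textbook knowledge, were over 10 times higher in both libraries than in both astrocyte libraries (median FPKM 143 and 119 against 0.801 and 0.459). An exchange among the 3 labels would not by itself account for the microglial genes, since none of these labels is microglia. Whether labels were exchanged as well stays open. The inhibitory list lay above both libraries labelled inhibitory neurons in 4 of the 4 other libraries, at 7.48 and 8.55 in the astrocyte pair against 0.944 and 2.63. But 0 of the 2 inhibitory-labelled libraries had the excitatory or astrocyte list above the libraries that carry those labels. How far the level reflects the collection of the cells and how far a change in the microglia themselves stays open, since the immediate early and heat shock list is also highest in this pair, at 93.8 and 94.3. A biological difference between the labelled cell types was not tested apart from this.

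Nuclear copies of mitochondrial genes parted by cross. The copies are not independent of each other, so their number overstates the evidence. All near-identical ones lie in a single stretch of chromosome 1 (24611535 to 24616197), and the diverged ones on chromosomes 2 and 4 lie in clusters. A strain variant of the mitochondrial genome, which F1i and F1r animals inherit from different mothers, may send reads of one strain to diverged copies and reads of the other to near-identical ones, and 14 of the 16 copies parted that way in every cell type. A sequencing batch is argued against as the whole cause, since the astrocyte pair shares a tracking number and its median absolute log2 difference over the same copies was 3.57. The 10 splits of the 6 libraries are too few for a share under 0.05, with 18 genes for the real split and 18 for the highest other. Besides the real one, the 3 splits with 18 genes hold a single comparison in 2 forms, that of the excitatory libraries, which differ in tracking number, and the count of 18 is 0 without any one of the 4 neuron-labelled libraries and 132 and 136 without the astrocyte F1i and F1r library.

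Hits on chromosome 19 fell on 1 strain allele. From 35 Mb on, both copies of the chromosome may come from 1 strain in these animals, for example through a parent that was not fully of the other strain, since at most 0.838% of hits in any library fell on the other allele. Below 35 Mb it is argued against for the part as a whole, with at least 16.5% of hits on the other allele in every library and 8.36% without Malat1, while 54 of 278 genes there lie under 2% and stay open. A fault in the allele sequences the authors aligned to cannot be told apart from it. The median log2 number of hits per FPKM on chromosome 19 was 4.11, against a median of 3.29 and a highest value of 4.36 on the other autosomes. From 35 Mb on it was 4.35, close to that highest value, and below 35 Mb it was 3.91. On the X, 55.2%, 65.7% and 69.0% of hits in F1i were paternal at a Ddx3y FPKM of 19.6, 25.3 and 22.7 and an Xist FPKM of at most 0.647, although a male's X comes from the mother; whether reads on chromosome 19 were misassigned in that way, and any biological explanation, was not tested.

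For the strain effect, 1 of the 10 splits, the real one, gave as many genes, with 297 for the real split and 0 for the highest other; the splits are too few for a share under 0.05, and without the astrocyte F1r library 195 genes were called. For the parental effect, 26 of 31 codings of parent, the real one included, gave at least as many genes, with 1 for the real coding and 71 for the highest other. With unique hits 6 of 31 gave at least as many, with 3 for the real coding and 57 for the highest other, so that chance is not excluded by either. The codings with 71 and 57 genes are 1 coding, which differs from the strain coding in the inhibitory F1i library alone and points to the strain structure of the libraries. The count of 1 was 3, 4, 3, 2 and 3 without the excitatory F1i, inhibitory F1i, inhibitory F1r, astrocyte F1i and astrocyte F1r library.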

How the results depend on the processing

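The fits restricted to protein-coding genes, those without both inhibitory-labelled libraries and those without chromosome 19 were chosen after seeing the data. Of the values of named genes under the planned and added alternatives 521 kept their direction and side of the threshold, 160 kept direction alone and 0 reversed. These genes were chosen for groups without overlap, or for the same strain direction in all 6 libraries. A reversal was therefore hardly possible, and its absence says little about other genes. Where an arm keeps 1 library, that library is assumed to vary like the others. The cause of the changes below was not tested, except that smaller tests hold fewer genes or libraries by construction.

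Astrocytes against excitatory neurons gave 15 genes in the report, 1 with a pseudocount of 0.1, 0 with no filter, 6 among protein-coding genes alone, 43 without both inhibitory-labelled libraries and 0 to 57 without single libraries. Excitatory neurons against the inhibitory-labelled pair gave 970 in place of 3111 with no filter and 0 to 2179 without single libraries, and astrocytes against that pair 0 to 3779 in place of 4011. Among the 4 libraries of 1 tracking number the 3 contrasts gave 0 (astrocytes against excitatory), 946 (astrocytes against inhibitory-labelled) and 0 (excitatory against inhibitory-labelled). The cross gave 18 genes, 4 with no filter, 31 with no cell type covariate, 1 among protein-coding genes alone, 0 without both inhibitory-labelled libraries and 0 to 136 without single libraries.

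With the cross as a replicate block, astrocytes against excitatory neurons gave 0 genes, and the other 2 contrasts 3963 and 2906. The numbers were not shown to pair the libraries, since the correlation of deviations was 0.319, 0.129 and 0.0622 between the cell types.

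With unique hits plus 0.5, 3 genes had a parental and 459 a strain effect and 1 a difference between cell types, against 1, 297 and 0. Without chromosome 19 the parental and strain effects had 0 and 134 genes, and with hits and without chromosome 19 there were 4 with a parental effect, 281 with a strain effect and 1 with a difference between cell types. At 50 hits or more 190 genes had a strain effect. Without single libraries the ranges were 1 to 4 (parental), 195 to 263 (strain) and 0 to 61 (between cell types). With an estimated correlation 0, 0 and 0 lists passed camera in the 3 contrasts of cell types, against 6, 13 and 15. Genes past 2 SD in both crosses with the same parent numbered 0 in excitatory neurons, 0 in the inhibitory-labelled pair and 1 in astrocytes at 50 hits or more, and 0 in the inhibitory-labelled pair at 3 SD. The maternal share on the X at 50 hits or more was 33.3% in the excitatory F1i, 21.4% in the inhibitory F1i and 100% in the astrocyte F1r library, and no gene was left in the astrocyte F1i library.

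With 200 simulated genes changed by a log2 ratio of 1, the allele tests recovered 32.0% for parent and 29.5% for strain, and 0% for a parental effect in astrocytes alone; the number of hits was not varied.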

Other observations

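The genes in this part were chosen after their values were seen. Mki67, a marker of cycling cells, had an FPKM of 15.2 and 14.1 in the excitatory pair, 36.8 and 18.1 in the astrocyte pair and 0.688 and 1.53 in the inhibitory-labelled pair (log2 change of excitatory over inhibitory-labelled 2.92 ± 0.41, limma adjusted p = 0.0158). Top2a, a topoisomerase of dividing cells, had 25.1 and 15.9, 47.8 and 25.4, and 2.50 and 2.72 in the same order. Dcx, a microtubule protein of migrating neurons, had 31.4 and 34.7, 92.0 and 133, and 3.32 and 8.22, and was higher in astrocytes than in the inhibitory-labelled pair by 4.14 ± 0.43 (adjusted p = 0.0061). Sox11, a transcription factor of immature neurons, had 46.5 and 51.4, 115 and 106, and 2.93 and 9.16.

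Libraries with the same label differed in the levels of some markers of other cell types. Cx3cr1 had an FPKM of 74.4 in the excitatory F1i and 9.51 in the excitatory F1r library, and the microglia list 67.9 and 6.87. Mag, a myelin glycoprotein gene, had 228 in the astrocyte F1i and 42.1 in the astrocyte F1r library. In the inhibitory-labelled pair Pdgfra, a receptor of oligodendrocyte precursors, had 0.683 in F1i and 13.4 in F1r, and Cspg4 0.204 and 3.25.

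H13 had 722 hits, with 76, 38, 125, 127, 129 and 98 on the maternal and 17, 7, 12, 71, 17 and 5 on the paternal allele (excitatory F1i and F1r, inhibitory F1i and F1r, astrocyte F1i and F1r). Its maternal bias was weakest in the inhibitory F1r library.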
